A study of Ampelomyces quisqualis with 11 samples.

How the data were processed

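RNA was measured in Ampelomyces quisqualis, a fungus that parasitises powdery mildews, in 3 groups of 3 arrays. The groups were ungerminated conidia (asexual spores) collected at 0 h, a pool of conidia collected after 3, 6 and 12 h (early germination), and a pool collected after 24, 48 and 72 h (late germination). Another 2 arrays, of an earlier probe set, were hybridised with genomic DNA of the fungus. Groups and replicate numbers were taken from the sample labels. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

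The deposited RNA files are scanner output of 1-colour CombiMatrix arrays and hold a median intensity per spot and a median intensity of its surroundings on a linear scale, per the file headers. They also hold the percentage of a spot's pixels at the scanner limit, per the file headers. Per the labels' protocols, 5 µg of RNA was amplified and labelled with the dye Cy5. The genomic DNA files hold a median intensity per spot and no background column, per the file headers. The scanner and image software are not given in the sources used here. The authors also deposited a table of processed intensity values for each array design. In the table for the RNA arrays each column's median was 271.48, which is also the lowest value, and between 52.3% and 67.1% of a column's values lay at that floor. Ranks above the floor followed the scanner values of the same array, so the direction and the linear scale are known, while the normalisation method is not given in the sources used here. In the table for genomic DNA the column medians were 260 and 394.5, and its values lay close to the scanner medians.

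Each RNA array has 94928 spots, of which 90184 carry 31222 target probes of 35 to 40 bases, with 2 spots for 3815 probes, 3 for 27076, 4 for 329 and 5 for 2. There are 35 negative control probes on 315 spots. From the scanner values, background was corrected by normexp with an offset of 50 over all spots with a probe, values were taken to log2, 149 spots marked as bad in conidia replicate 3 were left out, control spots were removed, target spots were quantile normalised between the 9 arrays, and the spots of a probe were averaged. Saturated spots were kept. A linear model with 1 mean per group was fitted to all 9 RNA arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). Each contrast was tested two-sided with Benjamini-Hochberg adjustment over all 31222 probes, and a probe was called at an adjusted p under 0.05. A moderated F test covered both contrasts against conidia at once. The files give no transcript for a probe, so the probe is the unit throughout and several probes can belong to 1 transcript.

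A probe was counted as above background on an array where its log2 value before quantile normalisation exceeded the mean plus 2 SD of the negative control probes. A probe was counted as saturated on an array where over 50% of the pixels were at the scanner limit in all its spots. Classes over time combined the calls of the 3 contrasts. A change was classed as kept where both contrasts against conidia were called in 1 direction and late against early was not, progressive where all 3 were called in 1 direction, transient where an early change was followed by a called opposite change from early to late and the late level was no longer called in the early direction, returned in part where it still was, and late only where late germination differed from both other groups in 1 direction and early germination was not called. The overlap of the early and late changes was set beside 20 simulations of unchanged groups that share 3 conidia arrays.

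The files do not pair probe IDs with gene names, and no genome was used, so the 24 gene lists fixed beforehand, including those for plant and powdery mildew RNA, could not be applied. The rule for named probes, set before the data were examined, took the 2 largest rises and the 2 largest falls in early germination against conidia among called probes whose groups did not overlap. The test design and the alternatives were also set before the data were examined, except 3 alternatives chosen afterwards, namely a background from the negative controls, removal of base composition, and a block for the 3 arrays (1 per group) whose file opens with an empty line. The alternatives set beforehand changed the background correction, the normalisation, the filter on dim probes, the source of values, the spread model, the array weights, the replicate block, the fold threshold, the arrays in the fit and each array in turn.

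The fit was tested on simulated data for each contrast, with 200 of 31222 probes changed. The changed probes were drawn only from those above background in all arrays of at least 1 group. In early germination against conidia, 62% of changes of 1 log2 unit and 99% of changes of 2 were called in the right direction, and 8 unchanged probes were called. The shares were 49% and 98% in late germination against conidia, with 6 unchanged probes called, and 58% and 100% in late against early germination, with 16 unchanged probes called. The number of arrays limits the precision. These shares do not cover dimmer probes. Fewer probes were changed than were called in the data (2366, 4463 and 544 in the same order). The shares thus need not equal the sensitivity of the reported fit.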

Results

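Ampelomyces quisqualis grows inside powdery mildew fungi, and its strain AQ10 is sold for biological control. The strain on the arrays is not stated here. The expression arrays followed the first 72 h of A. quisqualis conidia near a host. A dialysis sack with a cut-off of 12000 Da held 60 leaf discs of Cucurbita pepo (zucchini) infected with the powdery mildew Podosphaera xanthii. The sack was placed in a stirred suspension of A. quisqualis conidia, so that small molecules could reach the conidia while cells of host and plant stayed apart. Ungerminated conidia (n = 3 arrays) came straight from 21-day-old plates, early germination (n = 3) pooled 3, 6 and 12 h, and late germination (n = 3) pooled 24, 48 and 72 h. Conidia held in suspension without infected discs were not analysed here, so each contrast against conidia combines time in suspension with exposure to the discs.

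Median raw intensity of the target spots lay between 401 and 763 per array, and that of the negative control spots between 258 and 632. Between 69 and 313 target spots per array were saturated. On average 43.95% of the 31222 probes were above background in conidia (SD 1.54, n = 3), 44.26% in early germination (SD 2.59, n = 3) and 40.63% in late germination (SD 0.387, n = 3). The early share did not differ detectably from that of conidia (two-sided exact permutation test, p = 0.8). The late share was below every conidia and early array, and p = 0.1 for both comparisons is the smallest value that exact permutation of 3 against 3 arrays allows. That order was lost with a threshold of the mean plus 3 SD, where late arrays lay between 30.14% and 32.19% and overlapped both other groups (two-sided exact permutation test, p = 0.8 against conidia and 0.5 against early germination). In all, 13009 probes (41.7%) were above background in all arrays of at least 1 group, and 12769 (40.9%) were never above it. Across probes, which are not independent replicates, arrays of 1 group correlated at a mean r of 0.964 in conidia, 0.967 in early and 0.961 in late germination (lowest pair 0.954). Conidia correlated with early germination at a mean r of 0.93 and with late germination at 0.906. Early and late germination correlated at a mean r of 0.949, and their closest pair (0.959) lay above the lowest pairs within conidia and within late germination. Of the 100 brightest probes of an array, conidia arrays shared 79.3 on average with each other, 51.9 with early and 48.1 with late arrays, while early and late arrays shared 68.3. Between 15 and 80 probes per array were saturated in all their spots, and their ranks among the brightest are not measured.

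The first comparison asks which transcripts change as conidia start to germinate. In early germination 1463 probes rose and 903 fell against ungerminated conidia, 7.58% of the 31222 tested. The median rise was 1.01 log2 units and the median fall was −1.21. Large falls outnumbered large rises, since 160 probes fell and 83 rose at least 4-fold, and 35 fell and 16 rose at least 8-fold. A switch from no array above background to all 3 was seen for 105 of the probes that rose, and the opposite switch for 45 of those that fell. Of the 100 probes brightest in conidia, a choice that favours falls, 30 fell and none rose, and of the 100 brightest in early germination, a choice that favours rises, 31 had risen. Of the called probes, 2291 (96.8%) were above background in all arrays of conidia or of early germination. Groups had no overlap for 2359 of them, against 24.1% of all probes and 10% by chance. With 3 arrays per group a call almost always brings such a separation, so it is no separate support for the calls. The balance of rises and falls depended on the scaling of the arrays. Rises were 61.8% of calls with quantile normalisation, 41.4% (218 rises, 308 falls) when arrays were scaled to their medians, and 26.6% (393 rises, 1082 falls) without normalisation. The total fell to 1518 without early germination replicate 1, and the rises to 868 without that array and to 930 without conidia replicate 1.

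**Figure D1:**
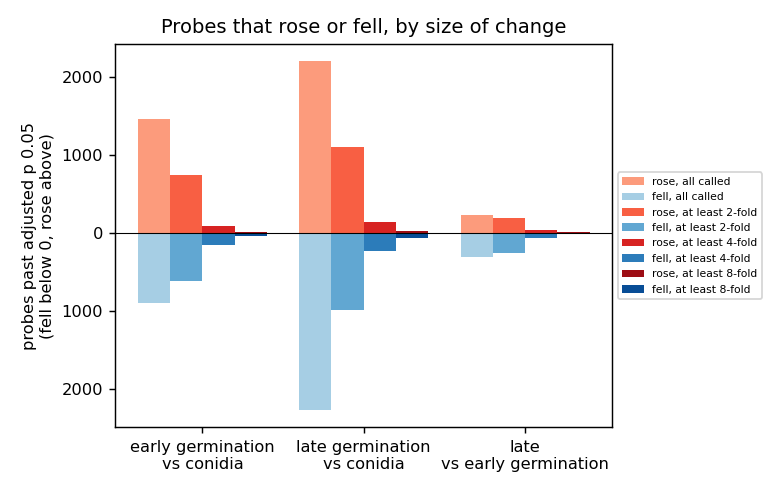
Number of probes past an adjusted p of 0.05 in each contrast (limma, n = 3 arrays per group), with rises drawn above 0 and falls below, for all calls and for calls of at least 2-fold, 4-fold and 8-fold. Late germination against conidia has the most calls (2195 rises, 2268 falls) and late against early germination the fewest (234 rises, 310 falls).

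The 2 probes with the largest measured early rises were Amp_7033 and Amp_5318. Amp_7033 (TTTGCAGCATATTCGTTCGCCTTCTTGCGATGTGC) had a normalised log2 intensity of 11.28 in conidia (SD 0.021, n = 3), 15.95 in early germination (SD 0.0622, n = 3) and 15.96 in late germination (SD 0.0304, n = 3). The probe was saturated on 2 of the 3 early arrays and 1 of the 3 late arrays, so the scanner limited the size of its measured rises of 4.66 log2 units early (SE 0.151, limma adjusted p = 8.7e-09) and 4.68 late (SE 0.151, limma adjusted p = 6.94e-09), and its early and late levels cannot be compared. Amp_5318 (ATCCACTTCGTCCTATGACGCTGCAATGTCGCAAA) stood at 10.37 in conidia (SD 0.132, n = 3), 14.96 in early (SD 0.143, n = 3) and 15.12 in late germination (SD 0.216, n = 3). It rose by 4.59 log2 units early (SE 0.177, limma adjusted p = 3.71e-08) and by 4.75 late (SE 0.177, limma adjusted p = 9.57e-09). Amp_5318 did not pass the test between late and early germination (limma adjusted p = 0.838).

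The 2 probes with the largest early falls were Amp_8381 and Amp_5171. Amp_8381 (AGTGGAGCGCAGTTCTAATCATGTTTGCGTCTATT) fell from 15.29 in conidia (SD 0.202, n = 3) to 9.898 in early germination (SD 0.41, n = 3), a change of −5.40 log2 units (SE 0.307, limma adjusted p = 6.32e-07). In late germination it stood at 11.6 (SD 0.686, n = 3), which was 1.70 log2 units above its early level (SE 0.307, limma adjusted p = 0.0118) and still below conidia (log2 change −3.70, limma adjusted p = 9.9e-06). Amp_5171 (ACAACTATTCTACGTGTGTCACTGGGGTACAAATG) fell from 15.42 in conidia (SD 0.483, n = 3) to 10.4 in early germination (SD 0.132, n = 3), a change of −5.02 (SE 0.234, limma adjusted p = 1.22e-07), and stood at 10.61 in late germination (SD 0.243, n = 3). All 4 probes were above background on every array. The rise of Amp_8381 between early and late germination was not past the threshold with arrays scaled to their medians (1.47, limma adjusted p = 0.395), in the authors' value table (1.68, limma adjusted p = 0.259), without early germination replicate 2 (1.49, limma adjusted p = 0.067) or with the background taken from negative controls (1.91, limma adjusted p = 0.0501).

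**Figure D2:**
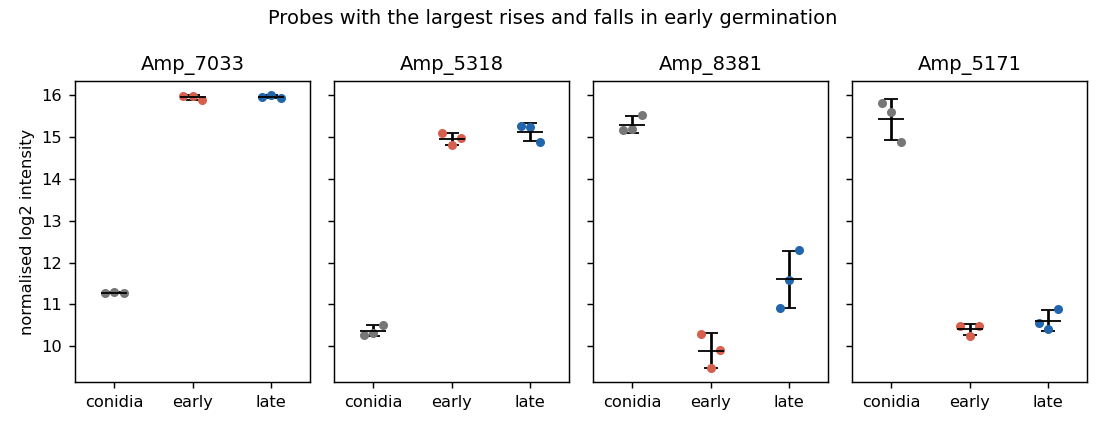
Normalised log2 intensity of 4 probes in conidia, early and late germination, with a point per array, a horizontal mark at the mean and bars of 1 SD (n = 3 per group). Amp_7033, which was saturated on some germination arrays, and Amp_5318 lie above conidia in both germination pools, Amp_5171 stays low, and Amp_8381 lies at 9.898 early and 11.6 late.

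The second comparison asks how the late pool differs from ungerminated conidia. In late germination 2195 probes rose and 2268 fell, 14.3% of those tested. The median rise was 0.999 log2 units and the median fall −0.94. At least 4-fold, 138 probes rose and 231 fell, and at least 8-fold 27 rose and 71 fell. Probes that went from no array above background to all 3 numbered 144, and those that went the opposite way 271. These switches were counted only at the mean plus 2 SD of negative controls. At that threshold late arrays had fewer probes above background in general, an order that was lost at 3 SD. Of the same 100 probes brightest in conidia 42 fell and none rose. Among the calls, 3814 (85.5%) were above background in all arrays of conidia or late germination, and the other calls were 211 rises and 438 falls of dim probes. Groups did not overlap for 4388 of the called probes, which again follows largely from the call, against 33% of all probes and 10% by chance. Rises were 49.2% of calls with quantile normalisation and 17.4% (593 rises, 2820 falls) without normalisation. The total fell to 2683 without conidia replicate 1 and to 2949 without late germination replicate 2. The even split also varied, with 59.6% rises (1870 rises, 1268 falls) without late germination replicate 1, 57.5% (1074 rises, 795 falls) in the authors' value table and 56.7% (2195 rises, 1676 falls) after removal of base composition.

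The third comparison tests the late pool directly against the early pool. Late germination differed from early germination at 544 probes, 1.74% of those tested, of which 234 rose and 310 fell. The median called rise was 1.40 log2 units and the median called fall −1.40. At least 4-fold, 41 probes rose and 63 fell, while at least 8-fold 12 rose and 4 fell. A switch from no array above background to all 3 was seen for 8 probes and the opposite switch for 32. The same limit of the background threshold holds for these counts. All 544 calls had groups without overlap, which again follows largely from the call, as did 14.5% of all probes. Rises were 43% of calls with quantile normalisation and 18.6% (22 rises, 96 falls) with arrays scaled to their medians. The total fell to 326 without early germination replicate 1 and to 272 without early germination replicate 2.

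Over the 3 groups at once, the moderated F test called 3939 probes (12.6%), and 2523 without conidia replicate 1. Changes of early germination that were also called in the late pool went almost entirely in 1 direction. Both contrasts rose at 1091 probes and both fell at 675, while 14 probes went opposite ways. The balance again depended on scaling, with 128 shared rises and 269 shared falls when arrays were scaled to their medians and 212 and 864 without normalisation. Shared rises numbered 675 without conidia replicate 1 and 688 without early germination replicate 1. Of the early rises 74.57% were also called as rises late, and of the early falls 74.75% as falls. Independent lists of these sizes would share 103 rises and 65.6 falls, and simulated unchanged groups against 3 shared conidia arrays shared 0.05 rises and no falls on average. Almost no probe is called in such groups, so that value does not show how far the shared arrays raise the overlap. Across probes, the log2 fold changes correlated at 0.778, against 0.499 in the simulation. Their covariance was 0.2245, against 0.0255 simulated, a difference of 0.199. The 3 conidia arrays were too few to split, so part of the overlap may come from their shared values.

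Of the 1766 probes called in 1 direction in both contrasts, 1672 (94.68%) showed no called difference between late and early germination. These kept changes were 1055 rises, with a median of 1.04 log2 units early and 1.09 late, and 617 falls, with medians of −1.23 and −1.37. With arrays scaled to their medians there were 125 kept rises and 260 kept falls. Kept rises numbered 651 without conidia replicate 1 and 671 without early germination replicate 1. Progressive changes were fewer. The median of 26 progressive rises was 1.06 early and 2.48 late, and that of 48 progressive falls was −1.47 early and −3.19 late. These classes were unstable, with 0 rises and 9 falls when arrays were scaled to their medians, 4 and 9 in the authors' value table, and 83 and 92 with array weights. Progressive rises numbered 11 without early germination replicate 1 or replicate 3, 12 without early germination replicate 2 or conidia replicate 2, 14 without late germination replicate 2, 15 without conidia replicate 1 and 52 without conidia replicate 3. Progressive falls numbered 30 without early germination replicate 1 and 23 without early germination replicate 2. Transient changes comprised 65 rises, with a median of 1.21 early and −0.159 late, and 64 falls, with medians of −1.48 and 0.10. Transient rises and falls numbered 12 and 10 with median scaling, 8 and 15 in the authors' value table, and 173 and 116 with array weights. Transient rises numbered 38 without early germination replicate 1 or late germination replicate 3, and without early germination replicate 2 there were 31 rises and 41 falls. Among them, 8 rises and 6 falls passed the conidia level and were called in the opposite direction late. A further 10 rises and 10 falls returned in part. Changes of late germination only comprised 107 rises, with a median of 0.0349 early and 1.46 late, and 163 falls, with medians of 0.00189 and −1.45. There were 11 such rises and 64 falls with median scaling, 23 and 25 in the authors' value table, 251 and 276 with array weights, 67 and 108 without early germination replicate 1, and 48 and 91 without early germination replicate 2.

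The most numerous class could not be placed in time. It held 991 rises and 1422 falls that were called in late germination against conidia but neither in early germination against conidia nor in late against early germination. Their early medians were 0.496 and −0.409 log2 units and their late medians 0.886 and −0.822. The early value had the sign of the late one for 97.4% of these rises and 97.6% of these falls, but these probes were chosen for a late call and both values share the conidia arrays. Over all probes 80.81% had 1 sign in both contrasts, against 66.74% in the simulated unchanged groups. Conversely, 307 rises and 164 falls were called early and in neither other contrast.

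**Figure D3:**
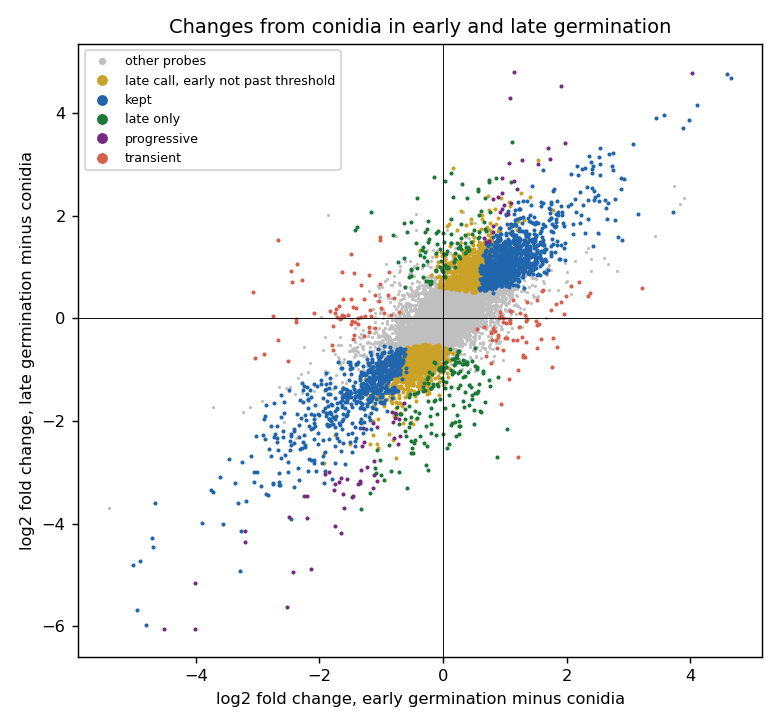
Log2 fold change of each probe against conidia in early germination (horizontal axis) and late germination (vertical axis), a point per probe, coloured by class over time. Kept changes (1055 rises, 617 falls) lie along the diagonal, late-only changes (107 rises, 163 falls) near the vertical axis and transient changes (65 rises, 64 falls) near the horizontal axis.

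The genomic DNA arrays bear on which probes could be measured. They carried 59611 target probes, and all 31222 probes of the expression array have an identical sequence among them. The 2 arrays correlated across probes at r = 0.949 (Spearman rho 0.939), with an SD of 0.682 for the log2 difference between them. Sorted by the mean of the 2 deposited genomic DNA intensities, the probes of the expression array and the 28389 others separated without exception. The dimmest probe on the expression array had a mean of 316.25 and the brightest probe left off it 316.125. The median log2 intensity was 9.39 for probes carried over and 6.69 for those left off. Genomic DNA intensity had little relation to RNA level across the probes of the expression array (Spearman rho 0.144). These probes hold only genomic DNA intensities from 316.25 up, and a range narrowed in this way can lower rho. Against the negative controls the arrays resolved little, since 3.17% of probes on the first and 2.96% on the second exceeded the mean plus 2 SD of control probes, some of which were bright.

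**Figure D4:**
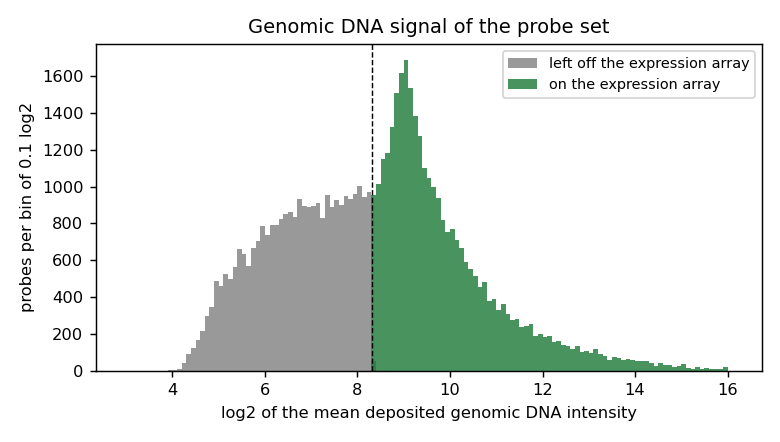
Number of probes by log2 of the mean deposited genomic DNA intensity (bins of 0.1) for probes left off the expression array (grey) and on it (green), with a dashed line at the dimmest probe carried over. The sets meet between 316.125 and 316.25 in linear units and do not overlap.

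Probes carried over were richer in G, with a mean G content of 27% against 23.2% for those left off, and slightly poorer in C (20.7% against 22.4%). Of the probes with more than 35% G, 83.9% were carried over (95% exact binomial interval 82.9 to 84.8). That share was 65.8% (64.9 to 66.7) at more than 30 and up to 35% G, and 42.1% (41.2 to 43.1) at more than 20 and up to 25% G. At 15% G or less it was 44.6% (43.3 to 45.8).

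**Figure D5:**
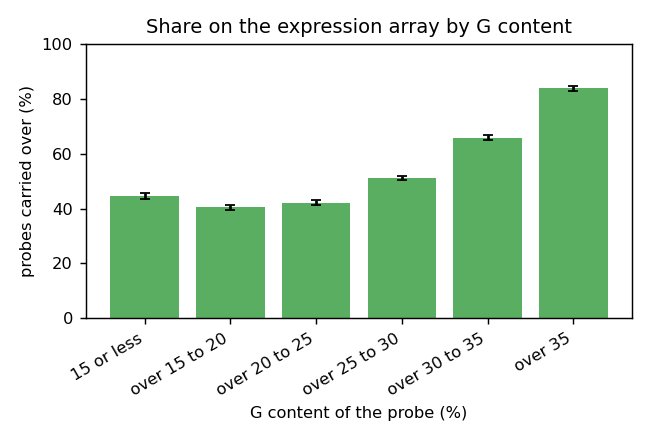
Percentage of the 59611 probes that were carried over to the expression array, by G content of the probe, with 95% exact binomial intervals as bars. The intervals treat probes as independent. The share lies between 40.4% and 44.6% up to 25% G and reaches 83.9% above 35% G.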

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

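Among the tests in this part, those of late rises and falls taken separately, of probes above background, and of the probes left off the expression array were chosen only after the result was seen.

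Late and early germination differed directly at 544 probes. One of them, Amp_8381, stood 1.70 log2 units higher late than early after its fall from conidia. The 6 arrays of a pair of groups can be split in only 10 ways, too few for a share under 0.05. In each contrast 1 split, the real one, gave as many calls. The real split gave 544 calls in late against early germination and the highest other split 3. In early germination against conidia the values were 2366 and 0, and in late germination against conidia 4463 and 3. For the F test over 3 groups, 1 of 100 splits drawn from the 280 possible, the real one, reached 3939 calls. The highest other split gave 1962, so no other drawn grouping of these arrays gave as many calls. As replicates may be technical, the splits cannot tell a difference between the groups from one between single preparations.

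In late germination against conidia, the log2 fold changes followed the base composition of the probe, which accounted for 24% of their variance among probes never above background and for 7.08% among probes above background. Non-specific signal that depends on composition may account for the relation in probes never above background. In probes above background, the part that composition accounts for had an SD of 0.217 log2 units (95% bootstrap interval 0.206 to 0.229). In probes never above background it was 0.144 (0.139 to 0.149). The intervals resample probes, which are not independent. The SD of all log2 fold changes was 0.817 in the former and 0.294 in the latter. Both SDs were larger above background, so this comparison cannot decide whether non-specific signal is the cause there. The relation was not particular to this contrast. Composition accounted for 16% of the variance never above background and 4.16% above it in early germination against conidia. In late against early germination the shares were 18.6% and 2.95%.

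After removal of base composition from each array, 74.3% of the 4463 late calls against conidia kept their direction, with 85.3% of the rises and 63.8% of the falls. Among dim probes the shares were 46% of 211 rises and 49.8% of 438 falls, and among the others 89.5% and 67.1%. The removal used 1 linear fit per array over all probes. A linear effect of composition common to all probes is thus not the whole cause of the rises, nor of the falls, of which 1446 of 2268 stayed called. An effect of another shape, or one larger in bright probes, would not be fully removed. The median of 323 lost rises went from 0.76 (median SE 0.205) to 0.541 (0.197) and that of 822 lost falls from −0.759 (0.204) to −0.49 (0.184), so the calls ended because the fold became smaller and not the spread larger. For the lost calls of either direction, composition cannot be told apart from a change of transcripts that share a base composition, because the removal takes out both. In early germination against conidia 92.4% of the calls stayed called after the removal, and in late against early germination 93.4%.

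Some negative control probes were bright with genomic DNA, in data outside the expression contrasts. The brightest reached an intensity of 24123 on the first array, where the target median was 250, and 14 of the 35 had a mean at or above the level that separated the probes carried over. Genomic DNA signal also rose with G content. Among 63 control probes the Spearman rho of G content and signal was 0.362 (permutation test, two-sided, p = 0.00393; Pearson r 0.34, p = 0.00637, and 0.29 without the 2 probes farthest from the median G content), across probes, which are not independent replicates. Hybridisation or labelling that follows G content whatever the target may account for that rise. A linear effect of base composition is not the whole cause of the probes left off, since it accounts for 14.3% of the variance of the log2 signal. At more than 20 and up to 25% G, 57.9% of probes were left off, a share that by itself does not test composition as the cause. Whether these came from the plant or the mildew in the sequenced RNA pool cannot be told apart from weak hybridisation, because no genome was used.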

How the results depend on the processing

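The background from negative controls, the removal of base composition and the empty-line block were chosen after seeing the data. The named probes' called changes kept their sign throughout, but early calls and calls shared by both contrasts against conidia turned from mostly rises to mostly falls with median scaling (218 against 308, and 128 against 269) and without normalisation (393 against 1082, and 212 against 864). Counts over the alternatives were within 1.5 times the reported one in 18 of 24 for early germination against conidia, 19 of 24 for late germination against conidia, 19 of 24 for late against early germination and 19 of 22 for the F test. With arrays scaled to their medians the counts were 526, 2535, 118 and 932 in that order, and 397 probes changed in 1 direction in both contrasts against conidia. Of these calls, 524, 1701, 118 and 889 were also called with quantile normalisation. This scaling moved the median of all probes up, by 0.0708 log2 units in early and 0.111 in late germination against conidia. Early calls nonetheless turned to mostly falls. Leaving arrays unnormalised moved that median by −0.151 early and −0.0563 late. Neither setting evens out the spread within arrays. Its log2 SD before quantile normalisation lay between 1.26 (late germination replicate 1) and 1.8 (conidia replicate 1). Without normalisation early germination had 1475 calls and the overlap was 1076. In the authors' value table, where most values lie at the floor, the counts were 1146, 1869, 89 and 1565 and the overlap was 893. With array weights there were 3711 calls early and 1160 in late against early germination. At least 2-fold, by its stricter criterion, left 1365 early, 2078 late and 922 in both. Beyond those constructions the cause was not tested.

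With 1 array left out, calls against conidia numbered 1518 to 2419 early and 2683 to 4765 late. Those in late against early germination numbered 272 to 752, and in the F test 2523 to 3926. The overlap was 1158 (without conidia replicate 1) to 1829. Fewer arrays lower the power, yet without conidia replicate 3 (array weight 0.442) counts rose to 752 and 1829 while others fell. The share of kept changes ranged from 91.4% with array weights to 98.2% in the authors' value table, but a change counts as kept where late against early germination was not called, so this share follows the power of that test and does not show stability. With the mean plus 3 SD of negative controls, 31.87% of probes were above background in conidia, 33.84% in early and 31.41% in late germination, and 0.307% and 0.391% on the genomic DNA arrays, which follows from the higher threshold.

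Only 1 of 9 arrays deviated most like one of its own number (same-numbered r −0.46 to 0.171). Deviations from means of few arrays cannot exclude pairing. With the replicate block the counts were 1877, 3360, 472 and 2988. The 4 named probes kept their direction and calls against conidia under all 23 alternatives. Not run were the alternatives for probes of 1 transcript and a slide or scan block, as the files give neither, those for gene lists, and a background correction for genomic DNA, which has no background column. Signal over background limits the dim probes, since 40.9% were never above the mean plus 2 SD of the negative controls. Of the 35 negative control probes, 1 exceeded that threshold and 2 exceeded the target median on all 9 RNA arrays. Bright controls raise the threshold.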

Other observations

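By group mean, 54 of the 100 brightest probes in conidia were also among the 100 brightest in early germination and 50 in late germination, while early and late germination shared 74. Of the 100 brightest in late germination, a choice that favours rises, 33 had risen against conidia, and 6 had risen against early germination. Saturation limits these ranks, since 32 probes were saturated on all arrays of conidia, 28 of early and 11 of late germination.

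Probes that overlap by at least 20 bases give an internal check, with values across probes, which are not independent replicates. For 104 pairs on the same strand, the log2 fold changes of late germination against conidia correlated at r = 0.938 (0.92 without the 2 farthest pairs; Spearman rho 0.866; two-sided permutation tests, p = 1e-04 for both, the smallest that 10000 permutations can give). The 12 pairs with both probes called all went in 1 direction. For 36 pairs on opposite strands r was 0.191 (permutation p = 0.263; Spearman rho 0.172, p = 0.306), and the median difference within a pair was 0.663 log2 units, against 0.141 on the same strand. Of 4 opposite-strand pairs with both probes called, 3 went in 1 direction and 1 in opposite directions.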
